A study of Hordeum vulgare with 18 samples.

How the data were processed

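RNA of barley shoots and roots was hybridised to 2-colour Agilent arrays of a custom design, 400 ng of RNA per labelling, per the labels' protocols. The untreated 0 h RNA was labelled with Cy3 and the salt RNA with Cy5 on every array, per the labels. For each array the authors deposited the scanner output of Agilent Feature Extraction, and its mean spot signals and median local backgrounds are linear intensity values with no normalization, per the file headers. The log ratio that the authors deposited with each spot is log10 of Cy5 over Cy3 after the software's own background subtraction, spatial and multiplicative detrending, and linear and lowess dye normalization, per the file headers. The table of values for the whole series, also deposited by the authors, holds these same log10 ratios, with a largest difference of 0 over all features, so its scale, centring and direction are those of the scanner software. The software version is 9.5.3.1 per the file headers and 9.1 per the submitters' processing notes. Medians of the deposited log10 ratios lay between -0.0176 and 0.

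Of 43900 features on each array, 1417 were controls and 42483 were probes with distinct names and sequences. The name columns of the files repeat the probe's clone name. None of the 42483 names (0) was found among the 58438 entries of the RefSeq gene table given for the species, so no gene names are used, and no genome was used here. The gene lists fixed before the data were examined, which search gene descriptions, could therefore not be filled and are void. In their place the peptides encoded by the probe sequences were searched for conserved motifs of stress-related protein families, and at most 7 probes matched any family.

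Slides and scans were read from the headers. The arrays lay on 6 slides. Replicate 1 was spread over slide 1 (shoot at 3 h alone) and slide 2 (shoot at 6 h, root at 3 h and root at 6 h), the 24 h arrays shared slide 3, and replicates 2, 3 and 4 had a slide of their own each. Replicate 1 at 3 h and 6 h, the 24 h arrays, and replicates 2 to 4 were scanned in 3 batches, the last with replicate 2 on a day of its own. A slide thus held both tissues and both times of a replicate in all but 1 case, and slide and replicate number mark nearly the same blocks.

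Signals were analysed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and drawn with Python 3.11.15 and matplotlib 3.10.9. Background was corrected with normexp and an offset of 50 over all spots, and log ratios were normalized by loess within each array, with control spots and spots marked as outliers by the software at weight 0. Outlier spots, 378 on the 16 arrays at 3 h and 6 h, were treated as missing, and saturated spots were kept. Probes were tested if well above background in either channel on at least 4 of the 16 arrays, which left 39395. limma's lmFit and eBayes were fitted to the 16 arrays with a mean per group of 4, giving 12 residual and 2.31 prior degrees of freedom and a median SE of 0.12 for a group mean. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 ratio of at least 1, that is 2-fold. The same fit gave the differences between 6 h and 3 h and between root and shoot. For untreated root against untreated shoot the Cy3 signals after normexp, loess and scaling of average signals between arrays (Aquantile) were averaged over the 3 h and 6 h arrays of a tissue and replicate number, leaving 4 values per tissue and 38717 probes. All p-values are two-sided.

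Precision depends on signal over background and on the number of arrays. Among probes called up, the untreated channel was not well above background on any array of the group for 9 in shoot at 3 h, 11 in shoot at 6 h, 14 in root at 3 h and 18 in root at 6 h. For such probes, and for tissue differences whose dim side was not well above background on any array, folds are given as "at least" values, from the mean of the brighter group against, per array, the higher of the dim probe's signal and the lowest signal among probes well above background. These bounds are open to dye bias, since no dyes were swapped. Spearman correlations between a probe's GC content and its log2 ratio lay between -0.15 and 0.08 over the arrays.

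The named-probe rule fixed before the data were examined asked for annotated genes, 10 rises and 10 falls per comparison. Without annotation it was reduced to the 2 largest rises and the 2 largest falls per comparison among called probes with all 4 replicates on the same side of 0 (for differences, among called probes), with the brightest probe standing for each group of probes. For the 24 h arrays the rule took the 2 highest and 2 lowest probes well above background in either channel. Also fixed before the data were examined were the groups, the tests, the thresholds and the alternatives, other than those marked as chosen later. The 24 h arrays had no test. Their sets of probes were described by the percentile of the median among 10000 random lists of the same size matched on mean signal.

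Replicate numbers come from the labels, which call the replicates biological. They were checked by correlating the arrays' deviations from their group means. Over replicates 1 to 4, r between the 3 h and 6 h arrays was 0.69, 0.70, 0.28 and 0.64 in shoot and 0.44, 0.70, 0.76 and 0.78 in root. Between shoot and root it was 0.26, 0.43, 0.22 and 0.22 at 3 h and 0.24, 0.34, 0.11 and 0.28 at 6 h, so the numbers were taken to pair the samples. The Cy3 signals of the 3 h and 6 h arrays of one tissue and number differed little, with a median absolute deviation of 0.072 to 0.091 in shoot and 0.052 to 0.078 in root on the log2 scale. Arrays of different numbers differed by 0.23 to 0.461 in shoot and by 0.268 to 0.465 in root. These arrays therefore held nearly the same untreated signal. The 24 h arrays differed from those of replicate 1 by 0.278 to 0.294, so their untreated signal was not the same to that degree. The sharing bears on 6 h against 3 h and on the residuals, which are pooled over the times as if independent.

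The fit was tested on simulated data in which known changes were added to probes for each comparison, with 39076 probes in the fit for the log ratios and 38716 for the untreated channel. Of the probes changed 2.5-fold, 4-fold and 8-fold, it recovered 83.6%, 92.5% and 97% in shoot at 3 h, 85.1%, 97% and 97% in shoot at 6 h, 91%, 97% and 97% in root at 3 h, and 91%, 95.5% and 97% in root at 6 h. The shares were 70.1%, 86.6% and 97% for shoot 6 h against 3 h and 68.7%, 86.6% and 97% for root 6 h against 3 h. They were 76.1%, 88.1% and 97% for root against shoot at 3 h, 73.1%, 89.6% and 97% at 6 h, and 82.1%, 94% and 100% for untreated root against shoot. Only 67, 67 and 66 probes per comparison were changed by these folds. False calls numbered 7 and 6 in shoot and 94 and 47 in root at 3 h and 6 h. They numbered 2 and 1 for 6 h against 3 h, 43 and 16 for root against shoot, and 15 in the untreated channel. In root at 3 h the 94 stood beside 61, 65 and 64 recovered probes. As a share of calls, false calls exceeded the adjusted p threshold in root, for root against shoot and in the untreated channel. They stayed under it in shoot and for 6 h against 3 h. The spread shared by all groups pools root with the less variable shoot, whose median residual SD was 0.19 against 0.24. With only the 4 arrays of the group in the fit, 3835 root probes were called at 3 h and 3672 at 6 h. That fit also has fewer residual degrees of freedom, so it does not isolate the effect of the pooling.

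The alternatives were the scanner software's log ratio, the table of the whole series, no background correction, median centring, scaling between arrays, no filter or a strict filter on dim probes, no minimum log2 ratio, a fit of only the groups compared, a trended and robust prior, the replicate number as a block, the slide as a random block, and each replicate left out in turn. For the untreated channel they were upper-quartile scaling of the processed signal, quantile normalization, no filter, no minimum, the 3 h arrays alone and the block. Chosen after seeing the data were tissue and replicate number as a block for 6 h against 3 h, leaving out root replicate 3, and leaving out replicates and blocking for the overlaps.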

Results

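The experiment followed gene expression in shoots and roots of barley (Hordeum vulgare, the Japanese malting cultivar Haruna Nijo) after young seedlings were moved into salt water. Seeds were germinated in water at 24 °C for 4 days with an 8 h day, 7 to a dish of 9 cm. Afterwards 3 germinated seeds were transferred to 4.5 ml of 0.2 M NaCl, and RNA was taken from shoot and root. Every one of the 18 microarrays was a 2-colour array. Its Cy3 channel held RNA of the same tissue at 0 h, before salt, and its Cy5 channel held RNA after 3 h, 6 h or 24 h in salt. Shoot at 3 h, shoot at 6 h, root at 3 h and root at 6 h had 4 biological replicates each, per the labels, and shoot and root at 24 h had 1 array each. A positive log2 ratio stands for more RNA after salt than at 0 h. The dyes were never swapped, and the 0 h control was not transferred to fresh water. The effects of dye and transfer thus lie in every ratio against 0 h together with that of salt. At 3 h and 6 h no control was matched for time of day, so clock time lies in those ratios too. By the hours of the design, 24 h falls at the clock time of 0 h.

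Each array carried 42483 probes of 60 bases, named after cDNA clones. The files do not pair these clone names with gene names, so results are given by probe, and probes that share a clone name or a run of 30 bases are also counted once, as a group of probes. There were 35250 such groups, 5745 of them with 2 or more probes. The first 2 probes of a clone name gave nearly equal log2 ratios over 5748 clone names, with r of 0.99 across probes in each of the 4 replicated groups. Where the first was called changed, the second was called too in 94.8% of cases in shoot at 3 h, 92.7% in shoot at 6 h, 95.1% in root at 3 h and 93.8% in root at 6 h, and in none of them in the opposite direction.

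In each replicate and at each time, the median signal of both channels was higher on the root than on the shoot array, and in each tissue it was highest at 24 h. The median Cy3 signal of replicates 1 to 4 was 756.4, 725.7, 701 and 680.2 in shoot at 3 h and 817.2, 706.2, 728.3 and 692.3 in shoot at 6 h. It was 1227, 1012, 940.6 and 1080.7 in root at 3 h and 1202.4, 996.8, 903.1 and 1079.5 in root at 6 h, with 1139.4 on the shoot and 1639.2 on the root array of 24 h. The median Cy5 signal was 1693.7, 1288.5, 1169.7 and 1251.9 in shoot at 3 h and 1632.9, 1245.3, 1319.9 and 1166.4 in shoot at 6 h. In root it was 2052, 1752.3, 1701 and 1779.6 at 3 h and 2231.9, 1529.9, 1844.3 and 1774.1 at 6 h, and at 24 h it was 2819 in shoot and 3491.7 in root. Between 79.8% and 88.6% of the probes were well above background in Cy3, and between 78.3% and 90.8% in Cy5. No array had more than 13 saturated probes in a channel. The number of arrays limits the precision.

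In shoots, more probes were called up than down after salt. At 3 h 1031 probes had risen and 194 had fallen at least 2-fold, together 3.1% of the 39395 probes tested and 921 groups of probes. At 6 h 778 had risen and 394 had fallen, in 893 groups. Rises were also larger than falls: 281 probes rose and 9 fell at least 4-fold at 3 h, and 186 rose and 20 fell as much at 6 h. At least 8-fold rises numbered 78 at 3 h and 57 at 6 h, against 0 and 4 falls. The excess of rises was smaller with no minimum log2 ratio, with 59.3% of the calls up at 3 h and 53.6% at 6 h. On single arrays at 6 h it was not always present: 716 probes were at least 2-fold up and 739 down in replicate 1, 1493 and 1792 in replicate 2, 1670 and 1184 in replicate 3, and 1158 and 540 in replicate 4.

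A pair of probes stood above all others in salted shoot at both times. Hv1054H21_1 rose by a log2 ratio of 6.42 ± 0.48 (SD, n = 4) at 3 h, or 85.4-fold, with an adjusted p of 1.1e-05 from limma, and was at 6.85 ± 0.57 at 6 h, with an adjusted p of 6.2e-06. Its sequence was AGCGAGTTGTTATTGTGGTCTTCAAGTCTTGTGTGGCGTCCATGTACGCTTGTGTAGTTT, and its spot was saturated on 1 of the 4 arrays at each time. Hv2083E12_1, with the sequence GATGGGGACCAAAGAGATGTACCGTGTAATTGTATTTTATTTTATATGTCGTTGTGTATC, rose 70.2-fold at 3 h (6.13 ± 0.56, adjusted p 4.1e-05) and 116-fold at 6 h (6.86 ± 0.63, adjusted p 1.5e-05). Its log2 ratio at 6 h was 7.80 in replicate 4 and between 6.51 and 6.58 in the other replicates. Both probes rose less in root, where the spread between replicates was wide: Hv1054H21_1 had a log2 ratio of 2.71 ± 2.28 at 3 h and 1.84 ± 0.88 at 6 h.

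The largest shoot falls were also shared by the times. Hv2106H03_1 was 6.71-fold lower at 3 h (-2.75 ± 0.47, adjusted p 1.4e-06) and 10.1-fold lower at 6 h (-3.33 ± 0.36, adjusted p 3.3e-07). This probe was abundant in untreated shoot, at a log2 signal of 12.5, and near background in untreated root, at 6.64, where its log2 ratios were -0.10 ± 0.46 at 3 h and 0.02 ± 0.41 at 6 h. Hv3085E19_1 was 7.1-fold lower at 3 h (-2.83 ± 0.82, adjusted p 0.0049) and 9.82-fold lower at 6 h (-3.30 ± 1.23, adjusted p 0.0018). Of the called shoot probes, 98.4% at 3 h and 99.1% at 6 h lay on the same side of 0 on all 4 arrays. The probes were called on these same arrays, so these shares and the medians per replicate partly follow from the choice. Within single replicates, each of which lay on its own slide or slides, the median log2 ratio of the probes called up at 3 h was 1.45, 1.39, 1.74 and 1.69 in replicates 1 to 4, and that of the probes called down was -1.25, -1.02, -1.10 and -1.52. At 6 h these medians were 1.18, 1.65, 1.65 and 1.38 for the probes called up and -0.98, -1.49, -1.47 and -1.21 for those called down. The shoot counts grew by over 1.5 times when the log ratios were scaled to a common spread over all arrays, to 1892 at 3 h and 1926 at 6 h, and with the scanner software's own log ratio to 1818 at 6 h. The number of falls depended most on such choices. It was 413 at 3 h and 786 at 6 h with the scaling, 448 and 708 with the scanner software's log ratio, 107 and 237 among probes well above background in both channels on all 16 arrays, and 127 at 3 h without replicate 4.

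**Figure D1:**
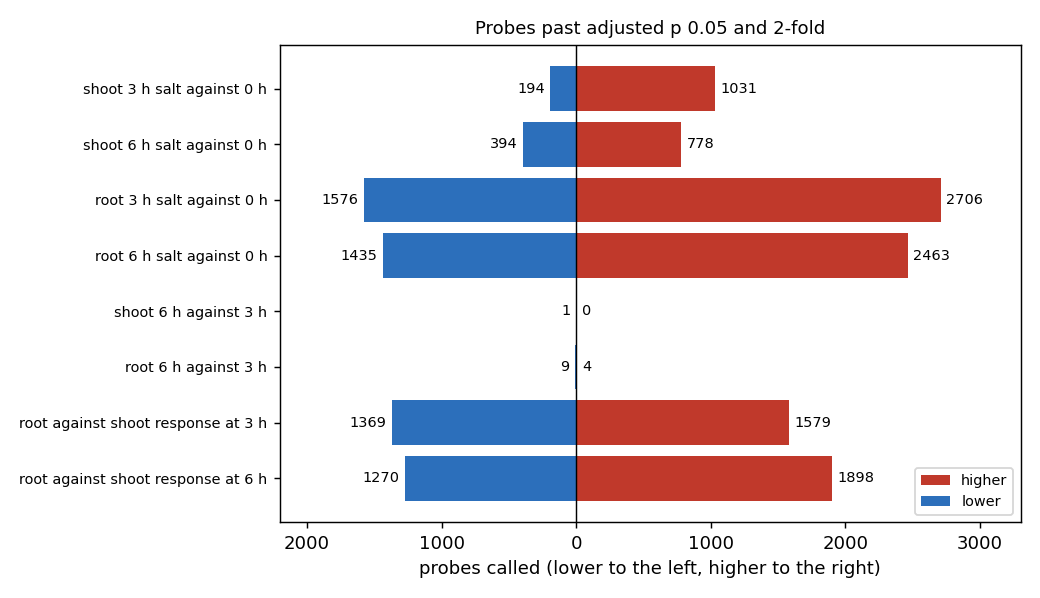
Number of probes called in each comparison of log ratios at an adjusted p under 0.05 and a change of at least 2-fold; bars to the right count probes higher, bars to the left probes lower, and the axis is the number of probes. Root bars at 3 h reach 2706 and 1576 probes, against 1031 and 194 in shoot, and the comparisons of 6 h with 3 h are close to 0.

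In roots, more probes changed than in shoots. At 3 h 2706 probes had risen and 1576 had fallen at least 2-fold, 10.9% of those tested and 3302 groups of probes, and at 6 h 2463 had risen and 1435 had fallen, in 3046 groups. The ratio of root to shoot calls was 3.5 at 3 h and 3.33 at 6 h. It was 1.53 and 1.55 when the log ratios were scaled to a common spread over all arrays, with 2890 and 2991 root probes called, a scaling that takes out a difference in spread by construction. With no minimum log2 ratio it was 2.35 and 1.95, and 54.2% and 54% of the root calls were up, against 63.2% at either time. With the scanner software's log ratio the root rises numbered 3039 and 2883 and the falls 2467 and 2206, and with the scaling 922 probes fell at 3 h. At least 4-fold rises numbered 727 at 3 h and 676 at 6 h, and falls of that size 151 and 197. The SD of the log2 ratios over all probes was 0.81 ± 0.05 (SD over 4 arrays) in root at 3 h and 0.78 ± 0.08 at 6 h, against 0.53 ± 0.04 and 0.53 ± 0.09 in shoot.

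Hv2012A11_1 rose most in root at 3 h, 66.7-fold (6.06 ± 0.81, adjusted p 6.1e-07), and was still 50.7-fold up at 6 h (5.66 ± 0.34, adjusted p 1.5e-06). Its sequence was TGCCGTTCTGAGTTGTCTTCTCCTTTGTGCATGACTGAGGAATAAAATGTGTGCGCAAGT. In shoot it rose 7.5-fold at 3 h (2.91 ± 0.84, adjusted p 0.0013), and at 6 h its log2 ratio of 1.32 ± 1.80 did not pass (adjusted p 0.071). Hv2115D22_1 followed in root with 49.9-fold at 3 h (5.64 ± 1.41, adjusted p 2.5e-07) and 27.6-fold at 6 h (4.79 ± 0.91, adjusted p 1.5e-06). The largest rises in root at 6 h were those of Hv2146B09_1 (6.35 ± 3.14, adjusted p 0.00018) and Hv2146A12_1 (5.93 ± 2.70, adjusted p 0.00015). Their wide SDs came from replicate 3: Hv2146B09_1 had a log2 ratio of 1.68 there and of 7.37 to 8.28 in the other replicates. Without replicate 3 their means were 7.91 and 7.25.

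Among root falls, Hv2009P09_1 was 13.7-fold lower at 3 h (-3.77 ± 1.18, adjusted p 1.5e-06) and 14-fold lower at 6 h (-3.81 ± 0.65, adjusted p 2.1e-06). It also fell in shoot, by 1.35 on the log2 scale at 3 h (adjusted p 0.014) and by 2.16 at 6 h (adjusted p 8e-04). Hv1009G20_1 was 9.67-fold lower in root at 3 h (-3.27 ± 1.45, adjusted p 2.6e-05), with its salt channel well above background on 3 of the 4 arrays. Its log2 ratio was -3.98 without replicate 1 and -4.41 with the scanner software's log ratio. At 6 h Hv2035E23_1 had the largest fall, 15.5-fold (-3.95 ± 1.29, adjusted p 1.6e-05). In untreated root its mean log2 signal was 12.23, against 6.60 in untreated shoot.

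Of the called root probes, 95.1% at 3 h and 96.7% at 6 h lay on the same side of 0 on all 4 arrays. As in shoot, the probes were called on these same arrays, so these shares and the medians per replicate partly follow from the choice. In replicates 1 to 4 the median log2 ratio of the probes called up was 1.57, 1.52, 1.56 and 1.55 at 3 h and 1.48, 1.68, 1.38 and 1.69 at 6 h, and that of the probes called down -0.93, -1.37, -1.62 and -1.43 at 3 h and -1.34, -1.26, -1.27 and -1.60 at 6 h. Among 755 probes at least 4-fold up in replicates 1, 2 and 4 at 6 h, 134 probes from 111 groups stayed below 25% of that log2 ratio in replicate 3, with a median of 0.43 against 3.65. By the same rule 129 of 789 probes were low in replicate 3 and 107 of 793 in replicate 2 at 3 h, and 58 of 680 in replicate 2 at 6 h. The median untreated level of the 134 probes on the 6 h array was 11.48 in replicate 3 and 7.2, 8.46 and 7.47 in replicates 1, 2 and 4. Without root replicate 3, a choice made after these values were seen, 3959 root probes were called at 3 h and 3893 at 6 h.

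**Figure D2:**
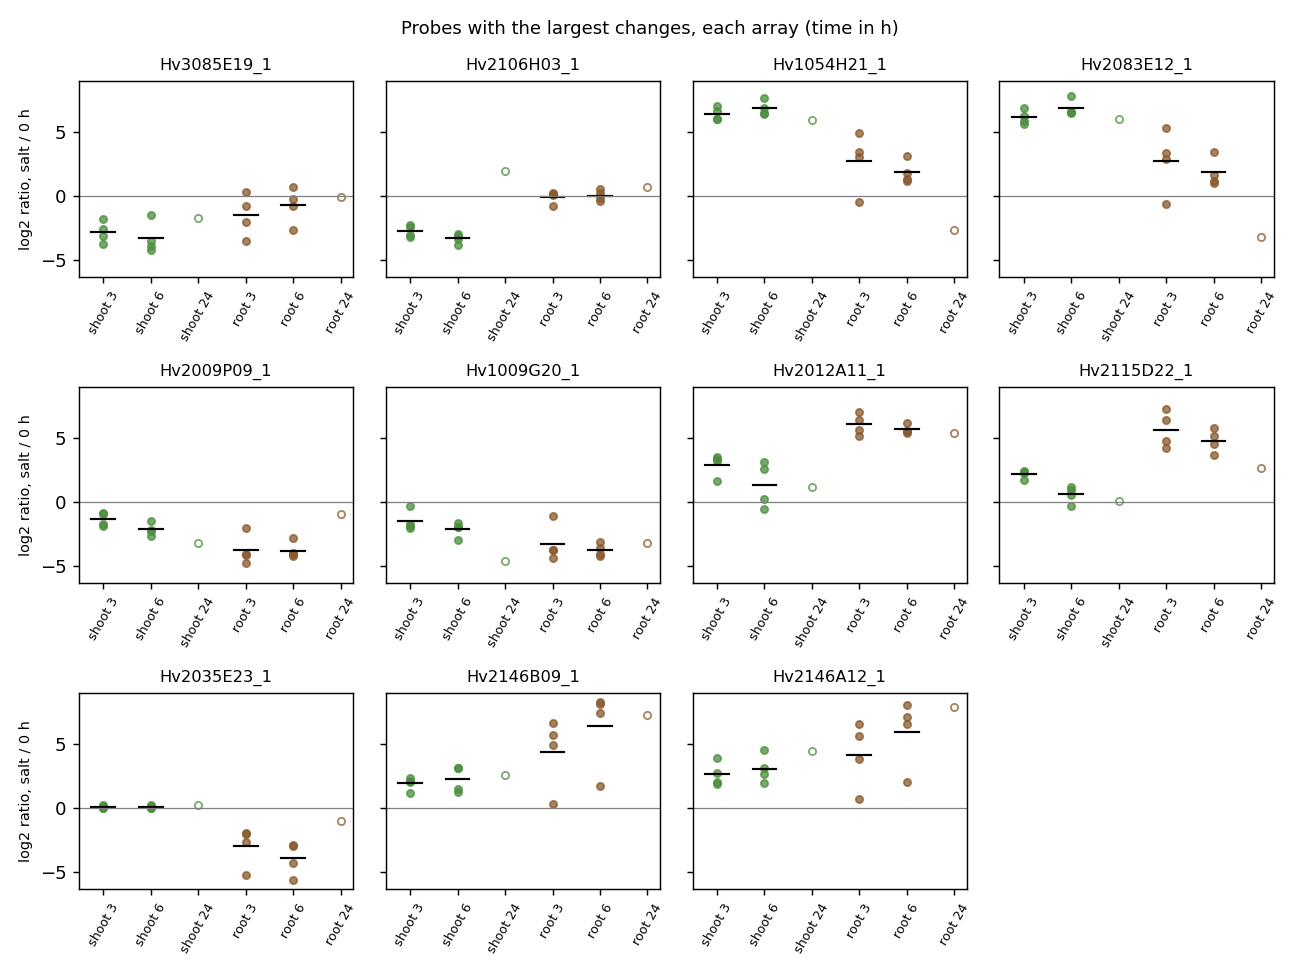
Log2 ratio of salt to 0 h (vertical axis) of the probes with the largest rises and falls in the ratios against 0 h, in each tissue and time in hours (horizontal axis); each point is an array, filled at 3 h and 6 h with 4 replicates and open at 24 h with 1, and the black line is the mean. In shoot Hv1054H21_1 and Hv2083E12_1 lie above 5 on every array, and in root at 6 h Hv2146B09_1 lies at 1.68 in replicate 3, below the other replicates.

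**Figure D3:**
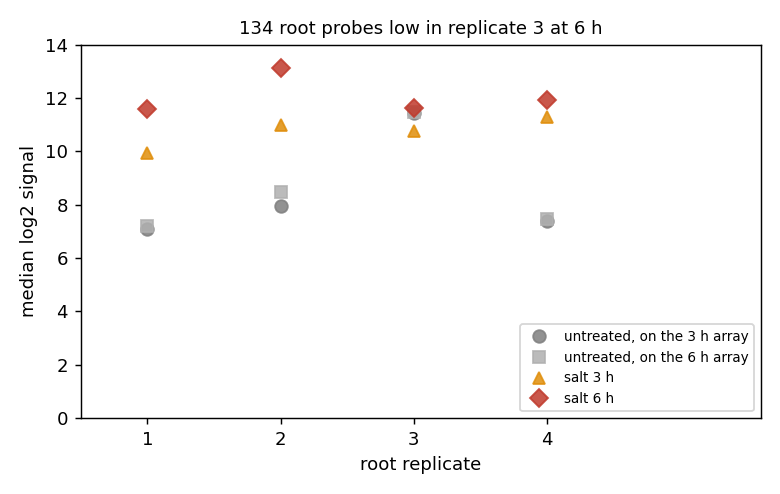
Median log2 signal (vertical axis) of the 134 root probes that stayed low in replicate 3 at 6 h, for each root replicate (horizontal axis); grey symbols are the untreated channel of the 3 h and 6 h arrays, coloured symbols the salt channel. The untreated level is 11.44 and 11.48 in replicate 3 and at most 8.46 in the other replicates, and the salt level at 6 h is 11.61 there.

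The ratios at 6 h were then set against those at 3 h within each tissue, to find probes whose response went on or turned back. In shoot 1 probe passed: Hv1081E20_1 fell from -1.33 ± 0.29 at 3 h to -2.75 ± 0.36 at 6 h, a difference of -1.43 with an SE of 0.17 and an adjusted p of 0.036. In root 13 probes from 9 groups passed, 4 higher and 9 lower at 6 h. Rises that shrank by 6 h included Hv2045D11_1, from 1.98 ± 0.20 to 0.18 ± 0.42 (difference -1.80, adjusted p 0.048), and Hv2128I23_2, from 1.71 ± 0.33 to 0.17 ± 0.38 (-1.53, adjusted p 0.011). For Hv2045D11_1 the mean log2 signal in root went from 16.09 to 14.97 in the salt channel and from 14.11 to 14.79 in the untreated channel. Part of its difference thus lay in the untreated channel. Hv2117C07_1 turned from -0.88 ± 0.27 to 1.05 ± 0.46 (1.93, adjusted p 0.049), and Hv3080D23_1 from -1.21 ± 0.66 to 0.33 ± 0.31 (1.54, adjusted p 0.048). At an unadjusted p under 0.05, limma gave 1548 probes in shoot and 4361 in root. Unchanged probes alone would give a share of 0.05 of the 39395 tested, and the shoot count is below it. This fit ignores that arrays of one tissue and replicate number deviated together, so a low count there does not show that nothing changed. With tissue and replicate number as a block, chosen later, limma gave 5669 probes in shoot and 10807 in root at that unadjusted p.

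These small counts depended on how the arrays were paired. Arrays of the same tissue and replicate number deviated together, and with the replicate number as a block 4 shoot probes and 91 root probes passed. With tissue and replicate number as a block, chosen after seeing that such arrays held nearly the same untreated signal, 21 shoot probes passed, every one of them lower at 6 h, and 351 root probes, 160 higher and 191 lower. Over the 191 lower root probes the median log2 ratio was 1.62 at 3 h and 0.25 at 6 h, and 123 of them were called up at 3 h, 73 of which were not called at 6 h. Over the 160 higher root probes the median was 0.38 at 3 h and 1.69 at 6 h, and 120 were called up at 6 h, 93 of them not called at 3 h. On the root array of 24 h the medians were -0.56 for the lower and 2.68 for the higher probes. On the other side, the counts dropped to 0 or 2 under several other settings, and leaving out any replicate gave 0 to 4 calls in either tissue.

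The responses of root and shoot to salt were compared by testing the difference of their log2 ratios. At 3 h 2948 probes differed, 1579 with the higher ratio in root and 1369 with the higher ratio in shoot, and at 6 h 3168 differed, 1898 and 1270. The balance at 3 h turned under some settings. It was 1746 and 1758 with the scanner software's log ratio, 1051 and 1078 with scaling between arrays, and 1419 and 1583 without replicate 1. Of those that differed, 1949 at 3 h (66.1%) and 2032 at 6 h (64.1%) were called in root and not in shoot, and 239 and 318 in shoot and not in root. Another 127 and 83 were called in both tissues in the same direction with unequal size, and 19 and 24 in opposite directions. The remaining 614 at 3 h and 711 at 6 h were called in neither tissue against 0 h.

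Opposite responses included Hv2051I23_1 at 3 h, which rose in shoot (1.61 ± 1.74, adjusted p 0.023) and fell in root (-2.85 ± 0.73, adjusted p 0.00017), a difference of -4.46 with an adjusted p of 0.00036. Its shoot replicates ranged from -0.57 to 3.5. Hv2072B15_1 rose in shoot at 3 h (3.11 ± 1.30, adjusted p 0.00076), and its root value of -1.14 ± 0.70 did not pass (adjusted p 0.072). The difference was -4.25 with an adjusted p of 0.00084. Hv2004D15_1 rose 28.6-fold in root (4.84 ± 0.77, adjusted p 3.2e-08). In shoot at 3 h it was well above background on 0 of 4 arrays in the untreated channel and on 2 in the salt channel, so its shoot response was not measured. Hv2012H01_2 rose 20.2-fold in root (4.33 ± 1.03) and stood at 0.52 ± 0.20 in shoot, a difference of 3.81 with an adjusted p of 3.4e-05.

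At 6 h Hv2083E12_1 and Hv1054H21_1 had root minus shoot differences of -5.03 (adjusted p 0.0016) and -5.01 (adjusted p 0.00085), the latter with a saturated spot on 1 of the 4 shoot arrays. Hv2117D09_1 rose 41.2-fold in root (5.36 ± 1.47) against 0.71 ± 0.47 in shoot, a difference of 4.65 with an adjusted p of 0.0012. Hv1119C16_2 rose 12.3-fold in root (3.62 ± 0.63) and had a log2 ratio of -0.86 ± 1.35 in shoot, a difference of 4.48 with an adjusted p of 0.0014. A dye effect of a probe would cancel in these differences if it were equal in both tissues, which was not tested. On the 7 pairs of root and shoot arrays of one replicate and time that shared a slide, and on the remaining pair, the SD of the log2 ratios was higher in root, by a factor of 1.19 to 1.8.

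The untreated channel alone separated the tissues strongly. Of 38717 probes tested, 8289 were at least 2-fold higher in untreated root and 7244 at least 2-fold higher in untreated shoot, 40.1% in all. Very large differences were more often toward shoot: 3042 probes were at least 8-fold higher in shoot and 1251 in root. Hv2022H16_1 was at least 1060-fold higher in root (adjusted p 1.6e-09) and Hv2064J08_1 at least 1050-fold (adjusted p 3.8e-10), both not well above background in any untreated shoot sample. Their untreated root log2 signals were 16.32 ± 0.55 and 16.36 ± 0.31 (n = 4). Hv3115B24_2 had a log2 signal of 16.98 ± 0.33 in shoot and 6.72 ± 0.40 in root (difference -10.26, adjusted p 1.2e-09). Hv1027M07_2 had 16.93 ± 0.09 in shoot and 6.69 ± 0.57 in root (-10.24, adjusted p 1.9e-09), with 7.54 in root replicate 3 and 6.31 to 6.48 in the others. In root these shoot probes were well above background on 2 and 3 of the 8 arrays. Both channels of an array share its loess fit, so this comparison across arrays rests on scaling their average signals to one distribution.

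Salt calls overlapped between times and between tissues. In shoot 646 probes were up and 143 down at both 3 h and 6 h, and in root 1843 were up and 1020 down at both, with 0 probes called in opposite directions at the 2 times in limma's tests. The 3 h and 6 h arrays of a replicate held nearly the same untreated signal, and when each time came from 2 replicates of its own, 0 to 2 shoot and 0 to 119 root probes were called in opposite directions. Between shoot and root 639 probes were up and 36 down in both at 3 h, and 431 up and 78 down in both at 6 h. Calls in all 4 groups numbered 353 up and 24 down. A total of 6046 probes were called in at least 1 of the 4 groups, 1608 in shoot, 5317 in root and 879 in both tissues. Of the probes called in all 4 groups, 74 up and 8 down had their 4 means within 0.5 of each other, which is also what a dye effect of the probe would give.

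Independent lists of these sizes would share 22.3 probes in the same direction between the shoot times and 226 between the root times, against 789 and 2863 observed. Between tissues they would share 78.6 at 3 h and 63 at 6 h, against 675 and 509. In 100 simulations of unchanged groups, which kept the deviations of the arrays of a replicate together, the mean number of shared calls was 0.51 between the shoot times, 24.15 between the root times, 0.07 between tissues at 3 h and 0.12 at 6 h. Few probes are called where none is changed, so these numbers give only the shared calls that the deviations alone produce. They say nothing about lists of the observed sizes. When the ratios at one time came from 2 replicates and those at the other from the other 2, between 39 and 476 calls were shared between the shoot times and between 1335 and 2716 between the root times. The same split gave 74 to 563 between tissues at 3 h and 38 to 581 at 6 h. Across probes, which are not independent replicates, the mean log2 ratios correlated with r of 0.88 between the shoot times, 0.90 between the root times, 0.50 between tissues at 3 h and 0.42 at 6 h. The simulations of unchanged groups gave a mean r of 0.58, 0.67, 0.28 and 0.24, and the split replicates 0.63 to 0.76, 0.59 to 0.85, 0.31 to 0.51 and 0.27 to 0.40. The covariances were 0.175, 0.431, 0.158 and 0.128, against simulated values of 0.0163, 0.0347, 0.011 and 0.00898.

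The 24 h arrays, 1 per tissue and without a replicate check, showed mostly the directions seen at 6 h. The 6 h calls were made for this purpose from replicates 2 to 4, so that they share no array with the 3 h and 6 h values of replicate 1 set beside the 24 h array. The 24 h arrays had a slide and a scan of their own, and their untreated signal differed from that of replicate 1 by 0.291 to 0.294 in shoot and 0.278 to 0.281 in root (median absolute deviation, log2), so a change between 6 h and 24 h also holds these differences. Such a change also holds clock time, which by the hours of the design matched that of 0 h at 24 h and not at 6 h. The 839 shoot probes up at 6 h had a median log2 ratio of 1.15 at 3 h, 0.99 at 6 h and 1.27 at 24 h, and 58.2% of them were at least 2-fold up at 24 h. The 542 shoot probes down at 6 h went from -0.44 and -0.62 to -1.26 on these arrays. In replicates 2 to 4, by which they were chosen, their medians at 6 h were already -1.37, -1.41 and -1.03. The 2456 root probes up at 6 h stood at 1.30, 1.40 and 1.31, and the 1428 down at -0.72, -1.19 and -1.05. Each of these 24 h medians lay outside the range of 10000 random lists of the same size matched on signal, which reached at most from -0.07 to 0.10. On the same side of 0 as at 6 h were 91.6% of the shoot probes up, 91.3% of the shoot probes down, 91% of the root probes up and 93.3% of the root probes down. At most 2.6% of the probes of any set were 2-fold changed in the opposite direction at 24 h.

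**Figure D4:**
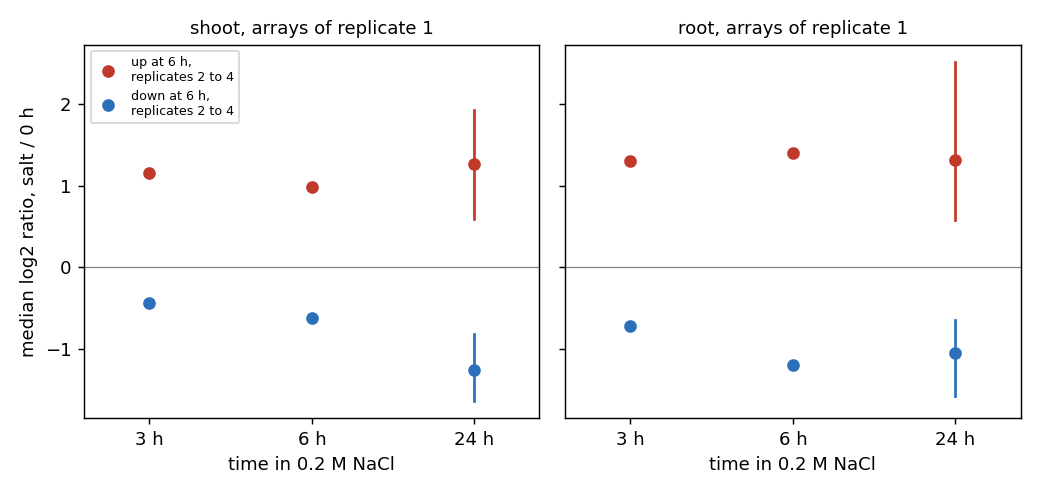
Median log2 ratio of salt to 0 h (vertical axis) on the arrays of replicate 1 at 3 h, 6 h and 24 h (horizontal axis), for the probes called up (red) and down (blue) at 6 h in replicates 2 to 4; bars at 24 h span the quartiles over probes. The shoot probes called down stand at -0.44, -0.62 and -1.26, and the root probes called up at 1.30, 1.40 and 1.31.

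Some single probes moved further at 24 h. In shoot Hv2083E12_1 (5.97) and Hv1054H21_1 (5.94) were again the highest, but below their 6 h values of 6.58 and 6.37 in replicate 1. In root the same probes stood at -3.20 and -2.63. Hv2106H03_1, the strongest shoot fall at 6 h, had a log2 ratio of 1.93 in shoot at 24 h. The lowest shoot values were those of Hv1015M10_2 (-5.09), which had been at 0.07 ± 0.16 at 6 h, and of Hv1088L06_1, at least 32.6-fold lower because its salt channel was not well above background. In root Hv3079F06_1 reached 8.55, or 375-fold, from 2.33 at 3 h and 6.93 at 6 h in the same replicate, and Hv2146A12_1 reached 7.91. Hv1062J10_1 (-4.92) and Hv1113M04_2 (-4.87) were lowest in root, with SDs of 4.09 and 4.46 between the 4 replicates at 6 h. Across probes the root 24 h array correlated with r of 0.48 with the 3 h and 0.73 with the 6 h array of replicate 1, and the shoot 24 h array with 0.35 and 0.47.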

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

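The slide tests for the difference between root and shoot and for the shared deviations of the arrays, and the test of mixed-in RNA of 3 h or 6 h, were chosen only after the results they bear on had been seen, and the other tests of this part before, except that the splits that part every pair were not fixed beforehand.

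Root and shoot differed in their response to salt by limma's test of the difference itself, with 2948 probes at 3 h and 3168 at 6 h. At 3 h the differences, root minus shoot, were -4.46 for Hv2051I23_1, -4.25 for Hv2072B15_1, 3.81 for Hv2012H01_2 and, as a fitted value only, 4.53 for Hv2004D15_1, whose untreated shoot signal was not well above background on any array. At 6 h they were -5.03 for Hv2083E12_1, -5.01 for Hv1054H21_1 (with a saturated spot on 1 of the 4 shoot arrays), 4.65 for Hv2117D09_1 and 4.48 for Hv1119C16_2. Between the times 1 shoot probe differed, Hv1081E20_1 by -1.43, and 13 root probes, among them Hv2045D11_1 by -1.80, Hv2128I23_2 by -1.53, Hv2117C07_1 by 1.93 and Hv3080D23_1 by 1.54. Part of the difference of Hv2045D11_1 lay in the untreated channel.

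More probes changed in root than in shoot, by a ratio of 3.5 at 3 h and 3.33 at 6 h, and of 1.53 and 1.55 with all arrays scaled to a common spread. A smaller spread between replicates in root was not seen, since the median residual SD in root was 1.24 times that in shoot. The fit pools the spread of both tissues, so the larger root spread can add root calls. In the simulated data false calls numbered 94 and 47 in root at 3 h and 6 h, against 7 and 6 in shoot. With only the arrays of the group in the fit, the ratio of root to shoot calls was 2.96 and 3. Brighter spots in root were excluded as the whole cause, since in each of 10 classes of equal brightness and at both times the SD of the mean log2 ratios was higher in root, by a factor of at least 1.24. Slide and scan were excluded as well, since over 7 pairs of arrays that shared a slide the SD was higher in root by at least 1.19 times. These SDs also hold the spread between replicates, which was larger in root, so they do not measure the response alone. The direct contact of roots with the salt solution, which the design names, stays open and was not tested.

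In replicate 3 of root at 6 h, 134 of 755 probes that rose strongly in the other replicates stayed low, one of them Hv2146B09_1 at 1.68 against 7.37 to 8.28, and such probes were also seen on other root arrays, with 129 of 789 in replicate 3 at 3 h, 107 of 793 in replicate 2 at 3 h and 58 of 680 in replicate 2 at 6 h. A slide effect was excluded, since on the shoot array of that slide the shortfall of these probes was -14.3% of the root one, that is, of the opposite sign. A raised untreated level in replicate 3 fits: read on the separate 3 h array, it made up 85.5% of the median shortfall of 3.45, it was above the other replicates for 133 of the 134 probes, and the salt level at 6 h differed by -0.54. These probes were picked by replicate 3's own ratio, which favours a high untreated level there. A raised level was not particular to replicate 3. For the 58 probes low in replicate 2 the untreated level was 2.36 above the others, 81.6% of their shortfall. For the 5 and 32 probes low in replicates 1 and 4 this share was -12.9% and 32.9%. Salted RNA mixed into the untreated extract fits as well: the 621 other probes at least 4-fold up in the other replicates had an untreated level raised by a median of 0.68 (quartiles 0.29 and 1.33) in replicate 3, above the 0.5 set beforehand, while the same choice of probes gave -0.62, -0.06 and -0.45 in replicates 1, 2 and 4. By a later reckoning, RNA of 6 h would raise these other probes by 2.01 or more. RNA of 3 h would need a share of 1.45 or more, which is above the whole extract. RNA of 24 h, from 1 array, would need a share of 0.229 and raise the other probes by 1.18, inside the quartiles seen. This reckoning decides nothing, since the low probes were picked by replicate 3's own ratio. Seedlings already stressed at 0 h stay open too, since no sample of the design separates them from mixed-in RNA.

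Arrays of one tissue and replicate number deviated together at 3 h and 6 h. A shared slide was excluded as the whole cause, since the shoot pair of replicate 1 lay on different slides and had an r of 0.69, above 3 of the 7 pairs that shared a slide. A shared untreated extract fits: the covariance of the untreated channels made up 133.2% of that of the log ratios, a share above 100 because the covariances between channels were negative. The salt channels made up 66.8% by the same measure, so this share does not single out the untreated extract, and samples of a replicate may also be alike in salt. A state of the seedlings shared by the samples of a replicate stays open and was not tested.

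Among 40 groups of 4 values checked for a sample far from the others, 4 had one, where chance gives about 1 in 20, that is 2. Besides Hv2146B09_1, the correlation of root at 6 h with the rest of its group was 0.87 in replicate 1 and 0.75 to 0.76 in the others. The shoot log2 ratio of Hv2083E12_1 at 6 h was 7.80 in replicate 4 and 6.51 to 6.58 in the others. The untreated root log2 signal of Hv1027M07_2 was 7.54 in replicate 3 and 6.31 to 6.48 in the others.

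Counts of calls were set beside other splits of the same arrays. For the ratios against 0 h, the 8 choices of signs are too few for a share under 0.05. There the real signs, 1 of the 8, gave 1225 probes in shoot at 3 h, 1172 in shoot at 6 h, 4282 in root at 3 h and 3898 in root at 6 h, and the highest other choice gave 0, 0, 327 and 8. For root against shoot, the real split was the 1 of 35 that gave so many, a share under 0.05. It gave 2948 at 3 h, 3168 at 6 h and 15533 in the untreated channel, against a highest other of 0 each. Samples of one number were taken as pairs, so the 35 splits are not interchangeable and this share does not exclude chance. Among the 8 of these splits that part every pair of same-numbered samples, the real one gave the most and the highest other gave 0, but 8 are too few for a share under 0.05. For 6 h against 3 h, 8 of 35 splits gave as many calls in either tissue, with a real count of 1 and a highest other of 110 in shoot, and 13 and 1525 in root. That highest split set replicates 1 and 4 against 2 and 3, so it points to a structure of the samples by replicate number. The 35 splits ignore the pairs, so their share decides nothing about the times. Here too the real split gave the most of the 8 that part every pair, in each tissue, and the highest other gave 0. Since 8 are too few for a share under 0.05, chance cannot be excluded for 6 h against 3 h. The block by tissue and replicate number, chosen later, called 21 probes in shoot and 351 in root.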

How the results depend on the processing

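Tissue and replicate number as a block, leaving out root replicate 3 alone, and the block and left-out replicates for the overlaps were chosen after seeing the data. In all, 133 recomputed counts and 24 h medians stayed within 1.5 times the reported count or within the spread, and 40 counts did not. Of the recomputed values of named probes, 173 kept their direction and call, and 21 kept their direction only, which belong to the 5 probes named for 6 h against 3 h. The linear fold moved by over 1.5 times, to these log2 values, for Hv1009G20_1 (-4.41 with the scanner software's log ratio, -3.98 without replicate 1), Hv2115D22_1 in root at 3 h (6.38) and Hv2072B15_1 (-4.85) with the scanner software's log ratio, Hv2146B09_1 (7.91 and 5.71) and Hv2146A12_1 (7.25 and 5.22) without replicates 3 and 2, and Hv2117D09_1 (5.35) and Hv3085E19_1 in shoot at 6 h (-3.89) without replicate 3. With the scanner software's log ratio, and identically with the table of the whole series, 1818 probes were called in shoot at 6 h, 0 in shoot and 2 in root for 6 h against 3 h. Scaling between arrays gave 1892 in shoot at 3 h, 1926 in shoot at 6 h, a ratio of root to shoot calls of 1.53 and 1.55, and 0 in both tissues for 6 h against 3 h. For these differences the strict filter gave 0 and 2, a fit of only the groups compared 0 and 0, the replicate block 4 and 91, the slide as a random block 82 in root, and tissue and replicate number as a block 21 and 351. Without root replicate 3 the root difference gave 2. Where limma called 0, it gave 822 to 4461 probes at an unadjusted p under 0.05, and the lowest of these counts are under the share of 0.05 that unchanged probes would give. None of those fits had a block by tissue and replicate number, with which limma gave 5669 probes in shoot and 10807 in root at that p. The replicate block moved no other count by over 1.5 times. With no minimum log2 ratio, more probes pass by construction: 7973 (59.3% up, against 84.2%) in shoot at 3 h, 9018 (53.6% up, against 66.4%) in shoot at 6 h, 18708 and 17599 in root, 21 for root 6 h against 3 h, 9552 and 10247 for root against shoot, 28271 in the untreated channel, and overlaps of 5596 (shoot times), 13538 (root times), 4077 (tissues at 3 h) and 3907 (tissues at 6 h). Apart from that and the small counts of 6 h against 3 h, no setting moved the share of rises by over 10 points. Leaving out a replicate gave 0 to 4 calls for 6 h against 3 h in shoot and 0 to 4 in root, and moved no other total by over 1.5 times, but the shoot falls at 3 h from 194 to 127 without replicate 4. Falls, counted alone, also moved by over 1.5 times with the scanner software's log ratio (448 and 708 in shoot, 2467 and 2206 in root), with scaling between arrays (413 and 786 in shoot, 922 in root at 3 h) and with the strict filter (107 and 237 in shoot), and with scaling 1051 probes, not 1579, had the higher ratio in root at 3 h. The cause of the changes other than the one by construction was not tested. The gene list alternatives (estimated correlation, all probes, replicate block, left-out replicates) were not run, since no list could be filled. The number of arrays and the signal over background limit small changes and dim probes.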

Other observations

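The probe with an encoded dehydrin motif, singled out below, was chosen after its values were seen, and the tests of tissue marks before.

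Dehydrins, proteins that accumulate in plant tissue under water loss, carry a lysine-rich motif named the K-segment. Exactly 1 probe of the array encoded it, Hv2121F15_1, with the sequence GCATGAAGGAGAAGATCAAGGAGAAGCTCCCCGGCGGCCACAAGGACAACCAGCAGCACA. It rose in all 4 groups: by 1.98 ± 0.41 (SD, n = 4) in shoot at 3 h (adjusted p 0.002), 1.54 ± 0.58 in shoot at 6 h (0.0085), 2.52 ± 1.11 in root at 3 h (7.9e-05) and 2.85 ± 0.90 in root at 6 h (3.6e-05). Its values at 24 h, 1 array each, were 1.53 in shoot and 2.92 in root. Among 7 probes that encoded the EF-hand motif of calcium-binding proteins, 4 were tested and 1 was called in 1 group, Hv1048L18_1, which fell by 1.18 in shoot at 6 h (adjusted p 0.015). Only this family had enough matches to be used by the rule of the motif search. Among the unused families, a probe with a cytochrome P450 motif, Hv2060N05_1, was called up in shoot at 3 h (2.01) and in root at 3 h (2.71) and 6 h (1.11). The tested probes with kinase, thioredoxin and glycosyltransferase motifs were not called in any group.

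A hypothesis was that salt lowers the transcripts that mark a tissue. Probes at least 4-fold brighter in one untreated tissue than the other were taken from replicates 1 and 2 and followed at 6 h in replicates 3 and 4. In root the 2739 root probes lay -0.06 from the median of all probes, inside the bound of 0.3 set beforehand. In these replicates 471 of them were at least 2-fold up and 399 down on average. These were 17.2% and 14.6%, against 7% and 4.7% of all probes. A median near 0 therefore decides nothing there, and the hypothesis stays open for root. In shoot the 4619 shoot probes lay -0.31 from it, with medians of -0.33 in replicate 3 and -0.23 in replicate 4, and 341 of them were at least 2-fold down and 160 up, which is consistent with a small loss. At 3 h the shift was -0.24, inside the bound, with medians of -0.07 and -0.35 in replicates 3 and 4 and with 191 down and 184 up. At 3 h these were 4.1% down and 4% up, against 0.9% and 4% of all probes. At 6 h the shares of the shoot probes were 7.4% down and 3.5% up, against 1.5% and 2.9% of all probes. At 6 h camera gave an adjusted p of 5.2e-14 with its preset correlation and an adjusted p of 0.32 with an estimated correlation of 0.14, so the shift may be a movement of genes that vary together.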
